A study of Mus musculus with 6 samples.

How the data were processed

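RNA was measured in 6 libraries of the mouse macrophage-like cell line RAW264.7: 3 labelled as knockout of E4BP4, the bZIP transcription factor encoded by Nfil3, and 3 labelled control. Per the labels' protocols, the cells were untreated, total RNA was extracted, polyadenylated RNA was selected, and libraries were made with an NEBNext Ultra RNA kit. The kit as named in the labels does not mark strand, and whether the authors' counting used strand is not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. How the knockout was made, whether it was a clone or a pool, and whether replicates were separate cultures are likewise not given. The p-values therefore measure the spread between these libraries, which may be partly technical.

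The submitters' processing notes name bcl2fastq, STAR 2.7.5a, HOMER 4.11.1, DESeq2 and the mm10 genome build, without the role or order of each. The authors deposited a table of TPM values, read numbers scaled by transcript length and then by library, with 25124 gene symbols, each with 1 RefSeq transcript, its mm10 coordinates and its length. Of these symbols, 5642 were listed at 0 in all 6 libraries. The listed TPM values of each library summed to less than the full TPM total, so the authors scaled over more transcripts than were listed. A second table deposited by the authors held 24421 symbols with variance-stabilized log2 values per library, the log2 fold change of their own comparison, and its p-values and adjusted p-values. The exact transform behind those log2 values is not given in the sources used here. The header of that comparison reads WT vs. TG, while the library columns are named WT and KO. What TG stands for is not given, and TG was read here as the group labelled knockout. Both tables held 23553 symbols in common. How reads that match several paralogs were assigned is not given, so values of near-identical family members, such as the major histocompatibility genes, the Ifi200-type genes and Lyz1 with Lyz2, are uncertain.

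The test fixed before the data were examined was a count model, with limma on TPM as its stated replacement where no counts were given. The tables held no counts, so that replacement was used throughout. TPM values were kept where at least 3 of the 6 libraries reached a TPM of 1, a pseudocount of 1 was added, and log2 values were compared with limma 3.58.1 with a mean-variance trend in R 4.3.3 (two-sided, no covariates, Benjamini-Hochberg adjusted p under 0.05). All fold changes on the log2 scale are of log2(TPM + 1), which understates the change of low genes. They are signed as libraries labelled knockout minus libraries labelled control. Ratios given as fold are ratios of mean TPM. Counts of genes changed at least 2-fold instead take an absolute log2 fold change of at least 1 in the fit named. A low gene with a TPM ratio above 2 can therefore fall outside them.

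Each TPM value multiplied by the gene length fell on a whole multiple of 1 step per library. For 100% of the values checked the multiple was within 0.1 of a whole number, where chance would give 20%. The whole reads so recovered came to 18373052, 19867732 and 19546422 in the libraries labelled knockout and 18110568, 18104946 and 15615639 in the controls. They were used for the depth behind each value, for the spread between replicates, for a limma-voom fit and for a filter of at least 1 CPM in at least 3 libraries, never for the main result. A chi-square comparison of recovered reads gave 1.83 to 6.13 per degree of freedom between replicates of a group, so no pair agreed within sampling noise and all 6 libraries were counted. No column of per-sample values was left unused.

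Before the data were examined, 30 gene lists were written from textbook knowledge: clock and D-box factors, reported E4BP4 targets, lists of macrophage function, metabolism, stress and division, genomic neighbours of Nfil3, markers of other cell types, and RNA quality. The 27 lists with at least 5 tested members were compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01. The same was done for each of 20 chromosomes. Camera was repeated with an estimated correlation, and fry was run as a test of each list's own direction. Named genes followed a rule: Nfil3; the 10 highest and 10 lowest fold changes among genes with adjusted p under 0.05, no overlap between groups and a mean of at least 5 TPM in a group (written as 5 CPM and applied to TPM); and up to 2 members per list with the smallest adjusted p. Predicted genes, clone names and small RNAs were left out of the 20. Any other gene named in the text was chosen after its values were seen, and some results of single genes are not reported here.

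Positions along the genome were examined in 10 Mb bins of mm10 with at least 10 tested genes, against 1000 shuffles of fold changes over gene positions. Gene structure, length and GC content came from GENCODE M21 (GRCm38, the same assembly as mm10), and 99.4% of the tested genes had a GC value. The limma steps were tested on simulated data of 11257 genes made for the comparison of the libraries labelled knockout with the controls. They recovered 18.4% of genes changed 1.2-fold, 84% of those changed 1.5-fold, 96% of those changed 2-fold and 98% of those changed 4-fold, and called 0.21% of unchanged genes. The simulation changed 49 or 50 genes per fold besides a small shift of chromosome 7. Its replicates varied more than the biological coefficients of variation of 2.58% and 3.74% measured here over genes with a mean of at least 500 recovered reads. The shares recovered therefore need not hold for the real comparison. A simulated changed list had an adjusted p of 0.000677, and 0 of 50 unchanged lists were called at the adjusted p threshold of 0.05.

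Alternatives included other scalings, filters and pseudocounts, recovered reads, the deposited stabilized values, a replicate block, leaving out each library, and leaving out chromosome segments. The count models fixed beforehand were not run because no table held counts. A planned search of promoters for D-box sequences was not run because no genome sequence was used here. All 3 libraries of each group entered every comparison, unless a library was left out as an alternative.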

Results

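Transcript levels were compared between RAW264.7 cells labelled E4BP4 knockout (3 libraries) and control RAW264.7 cells (3 libraries). RAW264.7 is a macrophage-like line from a mouse tumour induced by Abelson leukaemia virus, and E4BP4, the product of Nfil3, is a bZIP factor that binds D-box elements and mostly represses transcription. The deposited headers gave 21.7 M, 23.3 M and 22.7 M tags for the libraries labelled knockout and 21.4 M, 21.7 M and 18.4 M tags for the controls (M, mega). On log2(TPM + 1), Pearson correlations across genes were 0.994 to 0.996 for the 6 pairs of libraries within a group and 0.976 to 0.978 for the 9 pairs between groups, and genes are not independent replicates. The first principal component held 73.8% of the variance and separated the groups.

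Nfil3, the targeted gene, was higher in the libraries labelled knockout than in the controls. Its transcript (NM_017373) lies on the minus strand of chromosome 13 from 52967209 to 52981039 in mm10. GENCODE M21 annotates 2 exons, exon 1 from 52980861 to 52981073 and exon 2 from 52967209 to 52969021, with the whole coding sequence in exon 2, from 52967481 to 52968866. Nfil3 measured 105, 104 and 99.8 TPM in the libraries labelled knockout and 29.5, 29.9 and 31.0 TPM in the controls, from 3207, 3479 and 3230 against 922, 901 and 817 recovered reads. The means were 102.8 ± 2.65 TPM and 30.1 ± 0.803 TPM (SD, n = 3 each), a ratio of 3.41. In limma the log2 fold change was 1.74 (SE 0.0393, adjusted p = 4.96e-09), and the authors' deposited table gave 1.76. The level thus ran against a loss of the transcript under the knockout label, and groups are called by their labels throughout for that reason. A gene-level value cannot show an edit within the coding sequence, so it does not check whether the protein was lost, and every direction given here rests on the labels.

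**Figure D1:**
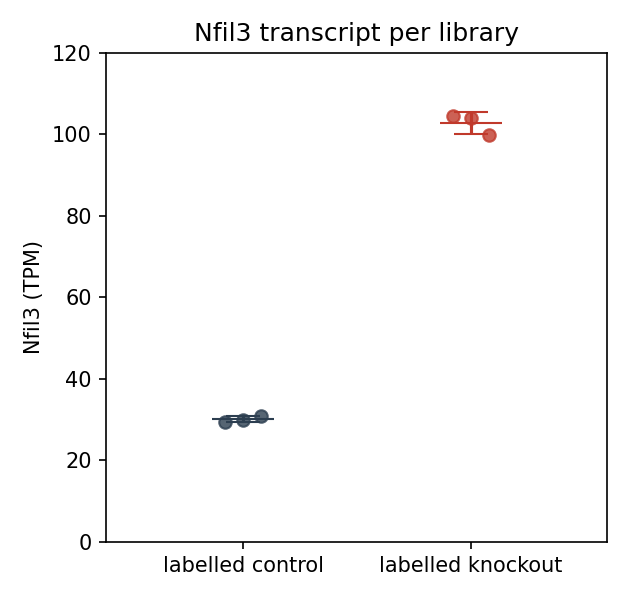
Nfil3 level in TPM for each of the 6 libraries, by labelled group, with a point per library and bars for the mean and SD of 3 libraries. The libraries labelled knockout sit between 99.8 and 105 TPM, and the controls between 29.5 and 31.0 TPM.

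The comparison asked which transcripts differ between the cells labelled E4BP4 knockout and their controls. Lists of interferon-induced, cholesterol synthesis, cell division, phagocytic and antigen presentation genes were lower in the libraries labelled knockout, and lists of ATF4 response and inflammatory mediator genes were higher. Camera called 11 of 27 lists in all, and with an estimated correlation it called 0, while fry, which tests only a list's own direction, passed 20. Of 11257 genes tested, 5639 (50.1%) passed in limma at an adjusted p under 0.05, with 3002 higher and 2637 lower in the libraries labelled knockout. The balance of directions was not stable across alternatives: upper-quartile scaling gave 2679 higher and 3063 lower, limma-voom on recovered reads gave 3064 and 3095, and removing the shift of chromosome 7 gave 2686 and 2763. Most differences were small: the median absolute log2 fold change of the called genes was 0.31. On log2(TPM + 1), 253 genes changed at least 2-fold, 119 upward and 134 downward. That balance turned without control replicate 1 (125 upward, 111 downward), 2 (122 and 110) or 3 (118 and 111). Without replicate 1, 2 or 3 of the libraries labelled knockout it was 96 upward and 143 downward, 102 and 141, or 96 and 148. The filter alone can move this balance: with a library left out, a gene reaching a TPM of 1 only in that group no longer had 3 such libraries. The 2-fold count was 409 with a pseudocount of 0.1, 433 on recovered reads with limma-voom and 100 on the deposited stabilized values.

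Atp9a, a phospholipid-transporting ATPase gene on chromosome 2 (168634438 to 168742136), rose most among the named genes, from 0.208 ± 0.0504 TPM in the controls to 15.4 ± 0.444 TPM in the libraries labelled knockout (SD, n = 3 each; log2 fold change 3.76, limma adjusted p = 2.89e-09). The control mean of Atp9a rested on about 10.3 recovered reads per library. Qprt, which makes a precursor of NAD from quinolinate, rose from 2.14 ± 0.433 to 29.8 ± 1.19 TPM. Chac1, a glutathione-degrading enzyme of the ATF4 pathway at 119351242 to 119354327 on chromosome 2, rose 9.95-fold, from 9.30 ± 0.677 to 92.5 ± 2.13 TPM (log2 fold change 3.18, limma adjusted p = 2.17e-09). Anpep, which encodes aminopeptidase N, rose 8.57-fold to 114.2 ± 5.61 TPM. Gadd45a, a growth arrest and DNA damage gene, rose 8.09-fold, and Cxcl2, which encodes a neutrophil-attracting chemokine, rose 7.58-fold to 50.7 ± 2.90 TPM. The other 4 genes of the upper 10 were Pla2g7 (platelet-activating factor acetylhydrolase), Rgs1 (a regulator of G-protein signalling), Chpf (chondroitin polymerizing factor) and Diaph2 (a formin), with log2 fold changes of 2.48, 2.46, 2.46 and 2.34.

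Pianp fell most among the named genes, from 15.0 ± 1.01 TPM in the controls to 0.111 ± 0.0448 TPM in the libraries labelled knockout (SD, n = 3 each; log2 fold change −3.85, limma adjusted p = 3.54e-09). It lies on chromosome 6 from 124998437 to 125003097, and its level under the knockout label rested on about 3.67 recovered reads per library. Ctsh, which encodes the lysosomal protease cathepsin H, fell from 8.28 ± 0.774 to 0.422 ± 0.0679 TPM. Fkbp11, an endoplasmic reticulum prolyl isomerase gene, was listed at 0.356, 0 and 0 TPM under the knockout label and at 7.16, 4.62 and 5.70 TPM in the controls. Cd84, a SLAM-family receptor gene, was 7.32-fold lower, and Tgfbi, a secreted matrix protein gene, was 6.68-fold lower. Sigirr, a negative regulator of interleukin-1 and Toll-like receptor signalling, fell from 9.16 ± 0.919 to 0.911 ± 0.0742 TPM. The Krüppel-like factor gene Klf2 fell from 23.6 ± 2.09 to 3.74 ± 0.441 TPM. Ifi44l, Vat1 and Cbr3 completed the lower 10, with log2 fold changes of −2.11, −2.07 and −1.98.

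**Figure D2:**
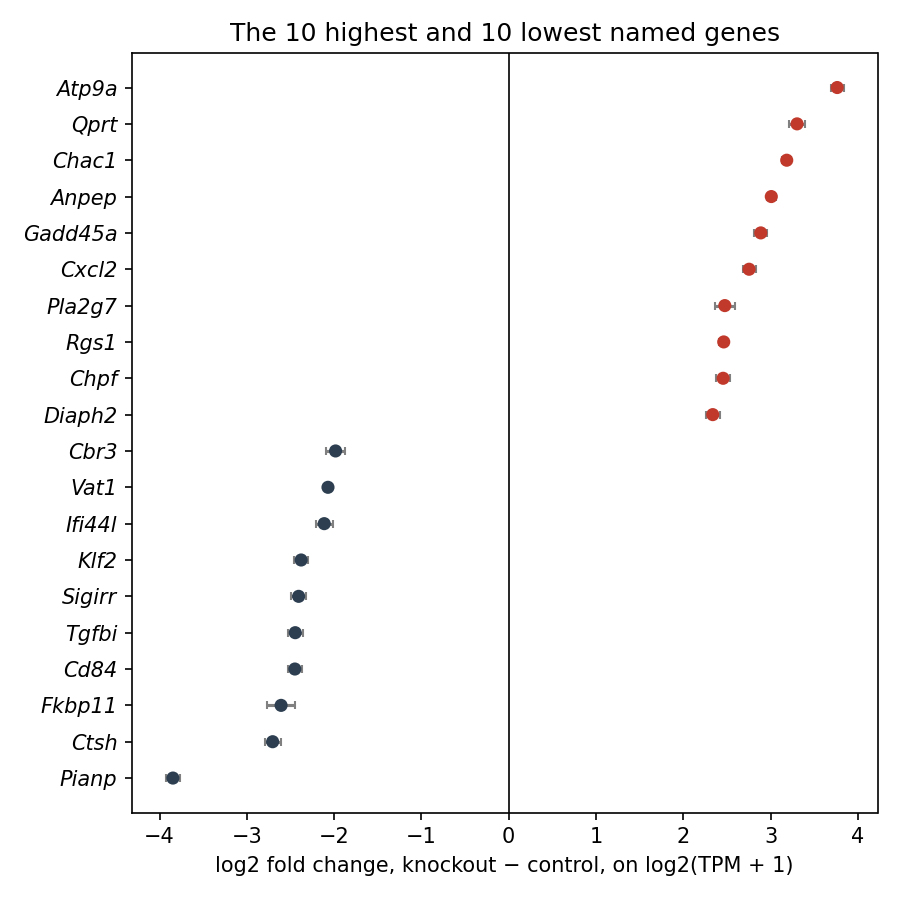
Log2 fold change on log2(TPM + 1), libraries labelled knockout minus controls, of the 10 highest and 10 lowest genes named by the rule, with points for the limma estimate and bars for its standard error. Values run from 3.76 for Atp9a to −3.85 for Pianp, and each bar is short against its fold change.

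Interferon-induced genes fell together. Of 36 tested members of the type I interferon list, 33 were lower, 0 were higher and 3 did not pass in limma; adjusted over the list alone, 34 were lower and 0 higher. The only member with a value above 0, Ifi47, had a log2 fold change of 0.08 and did not pass (adjusted p = 0.480). The list's median log2 fold change was −0.78, and 10 members fell by at least 1 on that scale. Ifi44 fell from 15.5 ± 1.52 to 3.48 ± 0.260 TPM, and Ifi27l2a, the most abundant of the members named here, fell from 300.2 ± 25.1 to 95.7 ± 8.39 TPM (SD, n = 3 each). Irf7, the transcription factor gene that amplifies interferon production, was 3.12-fold lower, and Isg15, which encodes a ubiquitin-like modifier, was 2.11-fold lower. Herc6 had a log2 fold change of −0.11 and did not pass (adjusted p = 0.121). Camera called the list at an adjusted p of 4.87e-16. The call was lost with an estimated correlation (adjusted p = 0.235 with an estimated correlation).

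Members of the unfolded protein and ATF4 list mostly rose, with some falling. Of the list, 24 of 32 tested members were higher, 7 were lower and 1 did not pass, with the same 24 and 7 adjusted over the list alone. The list's median log2 fold change was 0.59, and 9 members rose by at least 1 on that scale. Trib3, a pseudokinase gene induced by ATF4 and CHOP, rose 3.96-fold to 105.0 ± 1.57 TPM. Ddit3, which encodes CHOP, rose 5.03-fold to 84.3 ± 7.20 TPM, and Atf4 itself rose 2.01-fold to 720.9 ± 17.6 TPM. Herpud1 and Dnajb9, which act in degradation and folding of endoplasmic reticulum proteins, rose by 1.32 and 0.55 on the log2 scale. The 7 members that fell were Creld2, Hsp90b1, Sdf2l1, Pdia6, Pdia4, Hspa5 and Edem1, which also act on proteins of the endoplasmic reticulum, with log2 fold changes from −0.49 for Creld2 to −0.13 for Edem1. Xbp1 did not pass (log2 fold change −0.11, adjusted p = 0.0941). Camera called the list upward at an adjusted p of 4.02e-07, and with an estimated correlation the adjusted p was 0.238.

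Cholesterol synthesis genes fell by small amounts. Of 23 tested members, 21 were lower and 0 higher in limma, and 22 were lower adjusted over the list alone, with a median log2 fold change of −0.42. Acat2, which makes the first intermediate of the pathway, fell 2.02-fold, from 57.1 ± 0.668 to 28.3 ± 0.141 TPM, and Sqle, squalene epoxidase, fell from 219.0 ± 7.85 to 137.2 ± 2.66 TPM. Camera gave the list an adjusted p of 3.46e-10 (adjusted p = 0.238 with an estimated correlation). Genes of DNA replication and mitosis fell on balance: 28 of 45 were lower and 3 higher, with the same counts adjusted over the list alone and a median of −0.19. The 3 that rose were the replication genes Mcm3, Cdt1 and Rrm1, with log2 fold changes of 0.32, 0.16 and 0.16. Of other replication genes, Pcna and Mcm6 fell by little (−0.13 and −0.16), and Mcm2 and Mcm5 did not pass. Cdc20, the activator of the anaphase-promoting complex, was 1.75-fold lower and Aurka, the mitotic kinase Aurora A, 1.67-fold lower, whereas Mki67 measured 133.3 ± 3.99 against 134.2 ± 13.9 TPM and did not pass. Camera called this list at an adjusted p of 6.67e-07, against an adjusted p of 0.320 with an estimated correlation.

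Receptors and opsonins of phagocytosis were mostly lower under the knockout label. In the phagocytic, Fc and complement list 14 of 20 tested members fell and 2 rose, or 14 and 3 adjusted over the list alone, with a median log2 fold change of −0.36. Fcgr1, the high-affinity IgG receptor gene, fell from 40.2 ± 2.15 to 11.8 ± 0.646 TPM, and Cfp, which encodes properdin, fell from 281.8 ± 7.84 to 94.0 ± 4.56 TPM. The complement genes C1qa, C1qb and C1qc were 2.38-fold, 2.24-fold and 2.90-fold lower. Fcgr2b, the inhibitory IgG receptor gene, and C3 rose 1.55-fold and 1.79-fold. Camera gave an adjusted p of 2.96e-05 (adjusted p = 0.359 with an estimated correlation). In the antigen presentation list 12 of 22 fell and 2 rose, also adjusted over the list alone, with a median of −0.21. H2-T23 was 1.80-fold lower and H2-D1 1.33-fold lower, B2m fell 1.46-fold from 1349 ± 70.6 TPM, and H2-Ab1 rose from 0.200 ± 0.158 to 2.31 ± 0.156 TPM. Camera called that list at an adjusted p of 0.00172, against an adjusted p of 0.235 with an estimated correlation.

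Inflammatory mediators rose on balance, with chemokines split. Of 15 tested cytokines and mediators 8 were higher and 2 lower, in limma and adjusted over the list alone, with a median log2 fold change of 0.27. Il1rn, the interleukin-1 receptor antagonist, rose 3.42-fold to 28.4 ± 0.684 TPM, Ptgs2, the inducible cyclooxygenase, rose 1.85-fold, and Tnf rose 1.40-fold to 33.2 ± 1.85 TPM. Il15 and Casp1 were lower, with log2 fold changes of −0.26 and −0.37. Camera called the list upward at an adjusted p of 0.0168 (adjusted p = 0.359 with an estimated correlation). Of 14 chemokines 5 rose and 8 fell, or 5 and 9 adjusted over the list alone, and the list was not called (adjusted p = 0.370). Besides Cxcl2, Ccl3 rose 2.72-fold to 513.0 ± 8.20 TPM and Ccl4 rose 1.73-fold, whereas Ccl5 fell from 5.25 ± 0.873 to 1.09 ± 0.366 TPM and Ccl2 was 1.51-fold lower. In the NF-κB feedback list, which was not called (adjusted p = 0.0885), 14 of 25 rose and 6 fell, or 14 and 7 adjusted over the list alone, with Relb 1.99-fold and Dusp1 1.79-fold higher.

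Clock and D-box factors, the group nearest to E4BP4 in function, were called upward by camera on a minority of members. Of 14 tested members 6 were higher, 1 was lower and 7 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.16. Rora, a nuclear receptor that activates the clock, rose 1.88-fold to 4.42 ± 0.152 TPM. Nr1d2, Arntl, Cry1 and Bhlhe41 also rose, with log2 fold changes of 0.50, 0.49, 0.40 and 0.35. Tef, a D-box activator, fell (log2 fold change −0.29), and Dbp, another D-box activator, measured 2.33 ± 0.0795 against 2.56 ± 0.873 TPM and did not pass. Camera gave the list an adjusted p of 0.0295 (adjusted p = 0.585 with an estimated correlation), and the call ended without a filter on low values (adjusted p = 0.0773), with a filter of at least 1 CPM (0.0602) and with a TPM minimum of 5 (0.0518). Of 9 tested genes reported as E4BP4 targets, 1 rose and 3 fell, in limma and adjusted over the list alone, and the list was not called (adjusted p = 0.370). Bcl6, a transcriptional repressor gene, rose 1.45-fold. Il10, an anti-inflammatory cytokine gene, fell from 2.13 ± 0.680 to 0.320 ± 0.113 TPM, the latter from about 6.67 recovered reads per library.

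Metabolic and lysosomal lists had medians close to 0. The glycolysis and hypoxia list had 15 of 28 higher and 5 lower, also adjusted over the list alone, a median of 0.14 and a camera adjusted p of 0.0295 (adjusted p = 0.599 with an estimated correlation; the call ended at a TPM minimum of 5, adjusted p = 0.0518). Ero1l, an oxidase of the endoplasmic reticulum, rose 2.03-fold and the glucose transporter gene Slc2a1 rose 1.42-fold. The lysosome list had 18 of 37 lower and 9 higher, also adjusted over the list alone, a median of −0.09 and a camera adjusted p of 0.0295 (adjusted p = 0.626 with an estimated correlation). That call ended without replicate 1 of the libraries labelled knockout (adjusted p = 0.0524) and without control replicate 1 (adjusted p = 0.0723). Besides Ctsh, the protease gene Ctsl fell 1.42-fold. Oxidative phosphorylation genes were not called (adjusted p = 0.370), with 7 of 30 higher and 8 lower, also adjusted over the list alone, Uqcrc2 1.31-fold higher and Ndufa4 1.47-fold lower. Liver X receptor targets and lipid handling genes were not called (adjusted p = 0.240), with 6 of 25 higher and 11 lower, also adjusted over the list alone. In that list the fatty acid binding protein gene Fabp5 fell 2.24-fold and Lpl, lipoprotein lipase, fell 2.05-fold.

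The other lists of macrophage function were not called by camera and held members that moved both ways. Of 28 macrophage identity genes 8 rose and 15 fell, or 10 and 16 adjusted over the list alone (adjusted p = 0.146); Fcgr1 led the falls, the transcription factor gene Maf was 2.90-fold lower and the growth factor receptor gene Csf1r was 1.56-fold lower, while the lysozyme gene Lyz2 rose 2.08-fold to 2218 ± 49.2 TPM. Pattern recognition receptors split into 9 of 30 higher and 16 lower, also adjusted over the list alone (adjusted p = 0.0885), with Tlr2 2.21-fold higher and Tlr13 2.16-fold lower. All 12 tested alternative activation markers passed, 4 higher and 8 lower, also adjusted over the list alone (adjusted p = 0.0817), with the lipid receptor gene Trem2 1.41-fold and the scavenger receptor gene Msr1 1.56-fold lower. Chemokine and adhesion receptors had 5 of 16 higher and 7 lower, also adjusted over the list alone (adjusted p = 0.365), with Cx3cr1 4.45-fold and Itgb2 1.54-fold lower. In the osteoclast list 8 of 18 rose and 6 fell, or 9 and 7 adjusted over the list alone (adjusted p = 0.561), with Car2, a carbonic anhydrase gene, 3.64-fold and Mmp9, a matrix metalloproteinase gene, 2.83-fold higher. Matrix and protease genes had 4 of 19 higher and 6 lower, or 4 and 7 adjusted over the list alone (adjusted p = 0.561), with a median of 0.018, a mean of −0.024 and a downward test. Spp1, which encodes osteopontin, was 2.06-fold lower at 1029 ± 27.7 TPM.

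Among the remaining stress and signalling lists none was called. NRF2 and oxidative stress genes had 9 of 29 higher and 13 lower, or 10 and 13 adjusted over the list alone (adjusted p = 0.370), with the autophagy receptor gene Sqstm1 1.93-fold higher; its median was −0.07 while fry, a test of the list's own direction, pointed upward without passing (adjusted p = 0.356). The p53 and apoptosis list had 8 of 27 higher and 11 lower, also adjusted over the list alone (adjusted p = 0.558), and its median of −0.08, mean of 0.03 and downward test differed in sign. In it Bbc3, which encodes the apoptosis inducer PUMA, rose 2.93-fold beside Gadd45a. Immediate early genes had 13 of 27 higher and 8 lower, or 13 and 9 adjusted over the list alone (adjusted p = 0.325), with the feedback inhibitor gene Spry1 rising from 0.535 ± 0.0682 to 4.26 ± 0.0421 TPM beside the fall of Klf2. The 8 tested genomic neighbours of Nfil3 had 2 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.595; median 0.001, mean −0.18 and a downward test, which differ in sign), with Gadd45g 3.53-fold and Syk 1.35-fold lower.

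**Figure D3:**
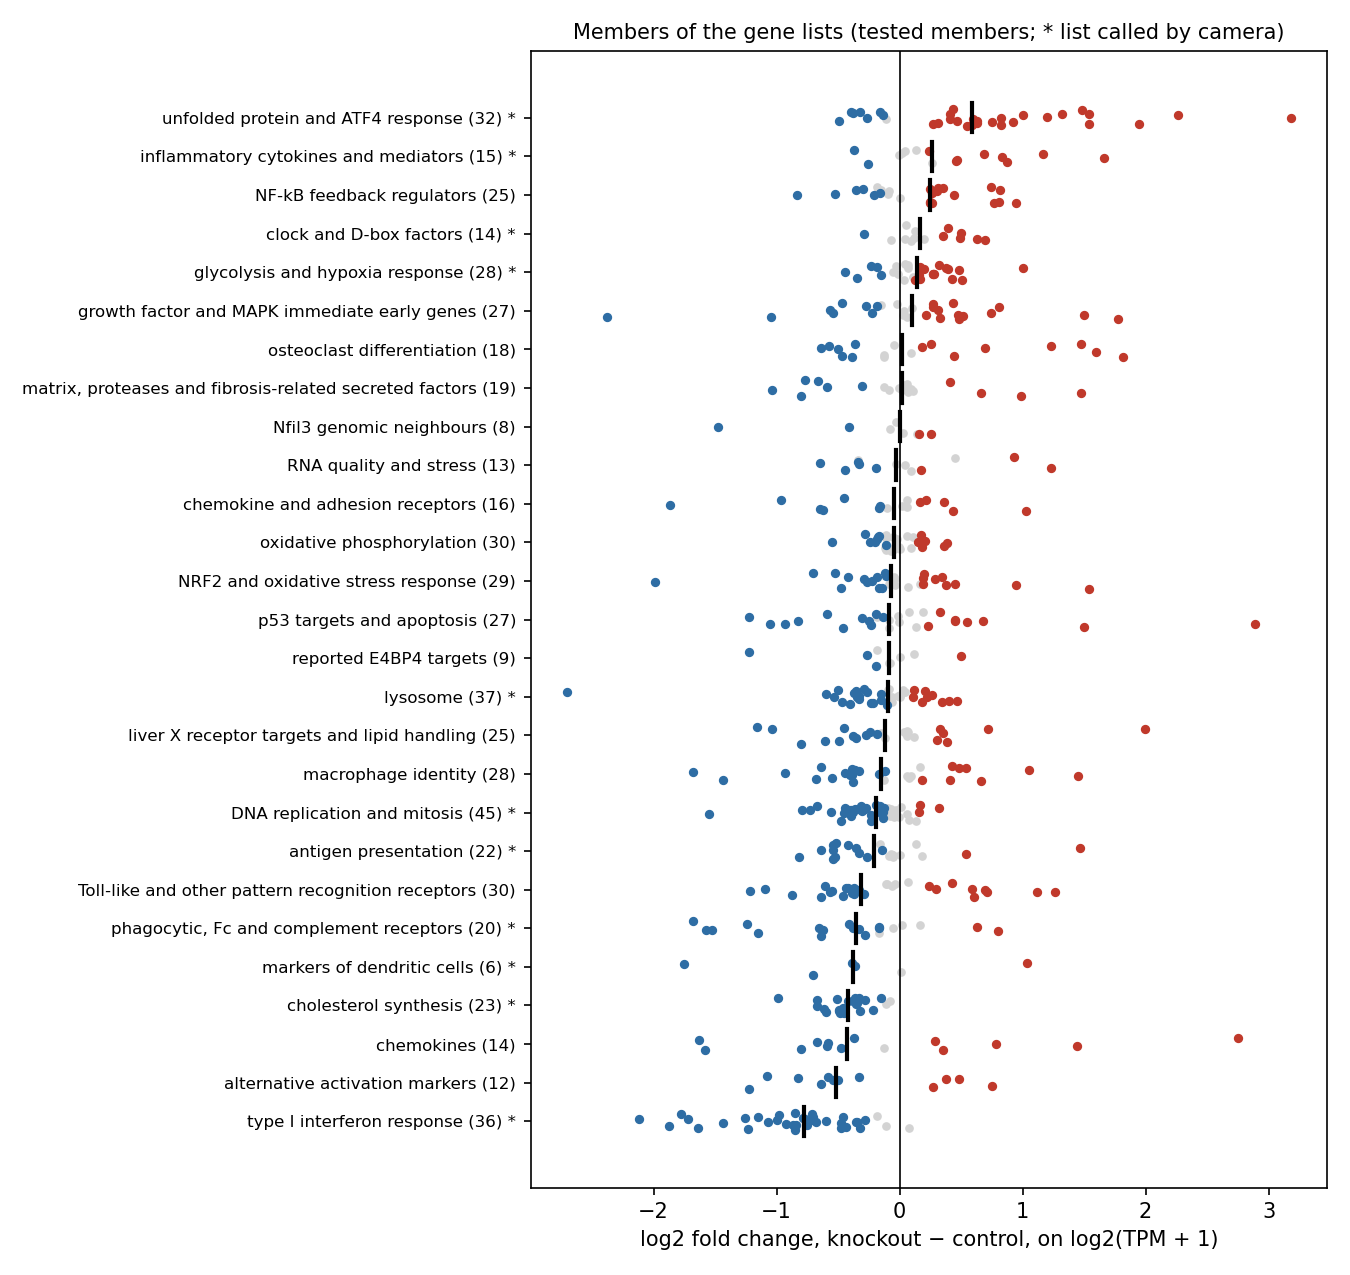
Log2 fold change on log2(TPM + 1), libraries labelled knockout minus controls, of every tested member of the 27 gene lists, with a point per gene (red higher, blue lower, grey not passing in limma) and a black bar at each list's median. The type I interferon list has its median at −0.78 and the unfolded protein and ATF4 list at 0.59, and a star marks the 11 lists called by camera.

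Few markers of lymphoid, granulocytic and stromal cells passed the filter on low values, whereas some dendritic cell markers were abundant in both groups. Of the T, B and NK cell markers only Lck was tested, and it rose 1.61-fold to 4.08 ± 0.109 TPM. Of the neutrophil and mast cell markers 2 were tested: Csf3r, which rose 1.88-fold to 3.81 ± 0.348 TPM, and S100a8, which did not pass (log2 fold change 0.05, adjusted p = 0.732); in both lists the counts were the same adjusted over the list alone. None of the 27 markers of fibroblasts, epithelium, endothelium and erythroid cells reached the filter, and the highest, Vwf, had a mean of 0.803 TPM. The dendritic cell list had 4 of 6 lower and 1 higher, also adjusted over the list alone, a median of −0.38 and a camera adjusted p of 0.0423 (adjusted p = 0.320 with an estimated correlation; adjusted p from 0.00248 to 0.216 over 18 alternatives). Batf3 fell 3.90-fold from 17.2 ± 0.825 TPM. Some members are not particular to this list. Bst2, also in the type I interferon list, fell 1.64-fold from 110.0 ± 5.23 TPM. Irf8, also in the macrophage identity list, fell to 87.9 ± 0.0925 TPM from 115.4 ± 4.67 TPM. In the list of RNA quality and stress 3 of 13 rose and 5 fell, also adjusted over the list alone, the list was not called (adjusted p = 0.605), and its median of −0.03, mean of 0.05 and downward test differed in sign. The nuclear RNA Neat1 rose 2.37-fold to 118.2 ± 5.12 TPM and the histone gene Hist1h1c rose 1.94-fold. Malat1, another nuclear RNA, was 1.28-fold lower.

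Genes of chromosome 7 were higher as a set in the libraries labelled knockout. The median log2 fold change of its 878 tested genes was 0.24, against 0.001 for all other genes, 81% of them had a value above 0, and 520 were called higher and 73 lower in limma. Among its genes with a mean of at least 10 TPM the median corresponded to a 1.21-fold difference. Camera over 20 chromosomes called chromosome 7 upward at an adjusted p of 5.99e-13 (adjusted p = 0.160 with an estimated correlation). Chromosome 5 was called downward (707 genes, median −0.05, adjusted p = 0.0354, and adjusted p = 0.992 with an estimated correlation), and that call ended without replicate 2 of the libraries labelled knockout, without control replicate 2 and without a filter on low values, each of which left 1 chromosome called. In 10 Mb bins, 14 of 14 bins of chromosome 7 lay at least 0.1 above the genome, from 0.15 to 0.42. On other chromosomes, runs of at least 3 shifted bins, passing over bins with under 10 tested genes, lay on chromosome 1 from 0 to 70 Mb (median 0.30) and from 160 to 190 Mb (−0.15), on chromosome 2 from 80 to 120 Mb (0.39) and from 140 to 190 Mb (−0.15), and on chromosome 16 from 40 to 90 Mb (0.13). Together with chromosome 7 these runs held 15.1% of the tested genes, 20.1% of the called genes and 19.8% of the genes changed at least 2-fold. Genes named above that lie on chromosome 7 include Qprt, Anpep, Relb, Bbc3, Arntl and Uqcrc2, all higher. They also include Sigirr and Irf7 (lower), and Mki67 and Dbp (not passing). Neither this list nor that of the segments, given next, covers every gene named above. Chac1 lies in the upward segment of chromosome 2, Atp9a, Trib3, Mmp9 (higher) and Aurka (lower) lie in its downward segment, and Cd84 (lower) and Fcgr2b (higher) lie in the downward segment of chromosome 1.

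**Figure D4:**
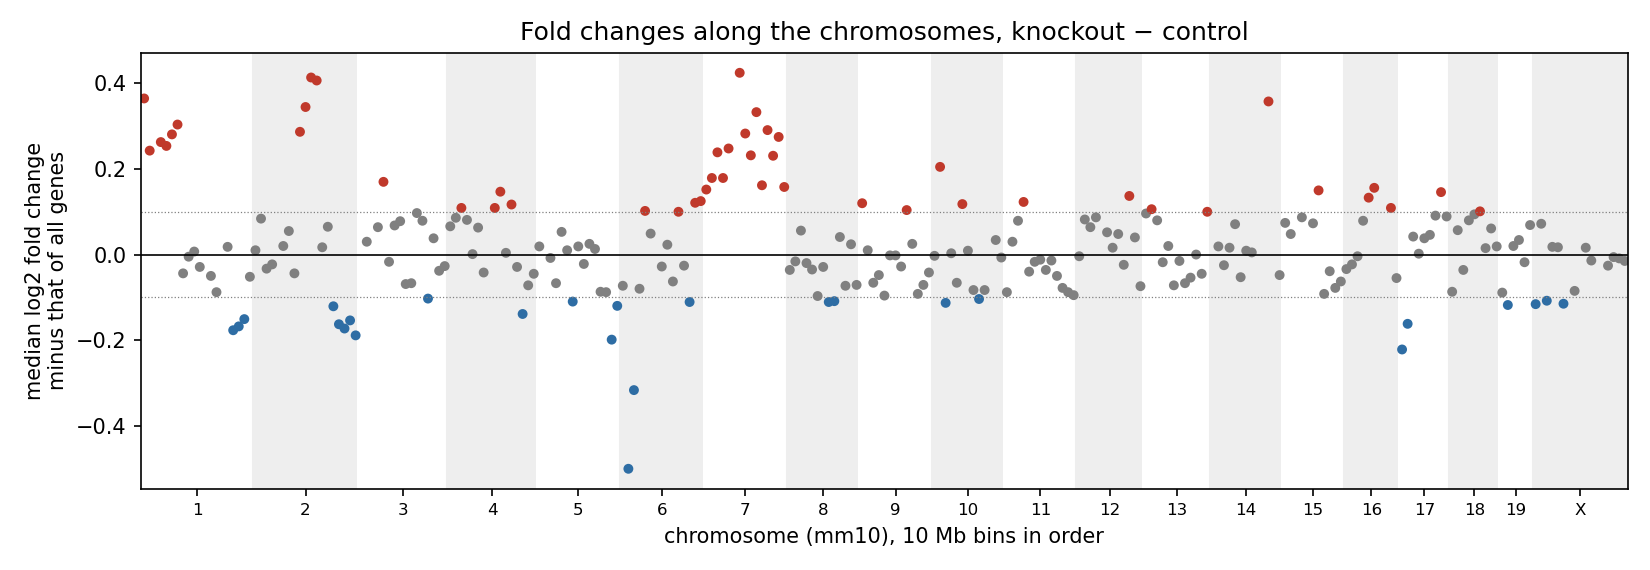
Median log2 fold change of tested genes in 10 Mb bins of mm10, minus that of all genes, along the chromosomes, libraries labelled knockout minus controls (red at least 0.1 above, blue at least 0.1 below). All 14 bins of chromosome 7 lie above, between 0.15 and 0.42.

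The authors' deposited table held its own comparison, with 5398 symbols at an adjusted p under 0.05, 2701 of them higher and 2697 lower in the libraries labelled knockout. Over 10734 genes present in both, the log2 fold changes of the authors' deposited table and of the limma fit had a Pearson correlation of 0.921 across genes, which are not independent replicates. Of these genes 4930 were called in the authors' deposited table and 5389 by limma; 4689 were called in both, and 4688 of those had the same sign. In the authors' deposited table Chac1 had a log2 fold change of 3.31, Atp9a 6.22 and Pianp −7.14, on a scale without the pseudocount used here.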

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

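The tests on Nfil3 and those on shifted segments outside chromosome 7 were chosen only after the results they bear on were seen. The others were recorded as written before. Those on chromosome 7, however, name that chromosome and its direction, and that on replicate spread uses recovered reads. These were therefore not fixed before the data were examined.

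In the authors' second table, 868 symbols are listed that do not occur as symbols among the TPM values, so the comparisons used none of these entries. Of these, 202 passed the authors' adjusted p, and they were picked out because no comparison read them under those symbols. Of the 868, 649 carry a transcript that the TPM values list under another symbol, and so do 158 of the 202, so most of these transcripts did enter the TPM values.

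Nfil3 was 3.41-fold higher under the knockout label, the reverse of a lost transcript. Extra copies of the wide region around its locus are argued against, since 61 tested genes within 5 Mb had a median log2 fold change of −0.08. That median cannot show extra copies of Nfil3 alone. An exchange of 1 library between the groups is argued against because the lowest library labelled knockout was 3.22 times the highest control. An exchange of the labels of both whole groups cannot be told apart from correct labels: the authors' deposited log2 fold change of 1.76 comes from the same libraries, and a gene-level value shows no edit. The header of the authors' comparison names its groups WT and TG, which does not settle the question. A biological explanation, that cells with an edited coding sequence make more of the transcript, for example through lost self-repression, may also apply and was not tested. Reads over an edited site, not analysed here, could separate exchanged from correct labels if the edit lies within the transcript. How the knockout was made, and so where any edit lies, is not given in the sources used here.

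Genes moved together along chromosome 7 and along 5 shorter segments of chromosomes 1, 2 and 16. GC content and gene length are argued against for chromosome 7, whose shift was 0.264 after both were accounted for and 0.241 before, and so are a few strong genes or a short region, since 100% of its 14 bins were shifted; a chance order of genes is argued against for the other 5 segments, since the highest number in 1000 shuffles was 1. A difference in copy number of chromosome 7 between the cells of the 2 groups is a candidate explanation, since all of its 14 bins were shifted. The spread (interquartile range) of its fold changes was 0.985 of that of the other chromosomes. An even shift of the whole chromosome would give that, but so would no shift, so the spread does not decide. On chromosome 4, which was not called and had a median of 0.02, the spread was 0.311 against 0.341 on the others. For the shorter segments as a group copy number cannot be told apart from other causes. The share of genes moving with the segment went from 87.8% down to 72.4%, short of the 75% set for every segment and above the 55% set against it. Taken singly, the upward segments of chromosomes 1 and 2 reached 87.8% and 87.6%, against 81% on chromosome 7. The downward segment of chromosome 2 reached 75.7%, while those of chromosome 16 (74.6%, upward) and chromosome 1 (72.4%, downward) stayed under 75%. Whether any difference in copy number came with the knockout or arose apart from it is open, since the origin of the cells under each label is not given in the sources used here.

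Called genes numbered 5639 of 11257 in this comparison of untreated cells of 1 line. The libraries can be split into 3 and 3 in 10 ways, too few to test for chance: 1 split, the real one, gave as many calls, and the highest of the others gave 1. GC content and gene length are argued against as the whole cause, since they accounted for 2.19% of the variance of fold changes. Replicates that vary little are a candidate explanation for the number, though not for the differences. The biological coefficient of variation was 2.58% under the knockout label and 3.74% in the controls, so small differences could pass. Both values cover only genes with a mean of at least 500 recovered reads, 6951 and 6622 genes. The spread of lower genes was not measured in this way. An effect of E4BP4 loss stays open beside other differences between the cells of the 2 labels, which the design cannot separate.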

How the results depend on the processing

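The scalings of TPM, the TPM minimum of 5, the fits on recovered reads and on stabilized values, and the fits without chromosome segments were chosen after seeing the data. The change of Nfil3 in knockout versus control libraries, as labelled, kept its direction and its call in all 19 alternatives (log2 fold change 1.52 to 1.77), and so did the 68 other named genes wherever tested (1243 of 1243 values). The number of called genes stayed within 1.5 times of 5639, from 4028 at an adjusted p under 0.01 to 6159 with limma-voom on recovered reads; leaving out each library gave 4700 to 5354. The number changed at least 2-fold, 253 on log2(TPM + 1), became 409 with a pseudocount of 0.1, 433 on recovered reads (175 upward, 258 downward) and 100 on stabilized values. The cause was not tested. Leaving out each library gave 229 to 244, with more upward than downward without any 1 control library and more downward without any 1 library labelled knockout. The filter on low values can move that balance by itself. Of 27 lists 11 were called; camera with an estimated correlation called 0 and fry 20, which asks another question of the list. Without the genes of shifted segments 12 lists and 4465 genes were called. Of 2 chromosomes called, 1 remained without a filter on low values, and leaving out each library gave 1 to 2; chromosome 7 was called each time, and the cause of the loss of chromosome 5 was not tested. No named gene or called list changed sign, but the balance of calls did under upper-quartile scaling (2679 higher, 3063 lower), limma-voom (3064, 3095) and without chromosome 7, its shift or all shifted segments. Of shared calls, 7 had the opposite sign with that shift removed and 2 on stabilized values. Medians of lists that were not called crossed 0 for chemokines (0.08 at a TPM minimum of 5), osteoclast and matrix genes, Nfil3 neighbours and RNA quality. Medians of called lists also changed in size over the alternatives. They ran from 0.116 to 0.4 for inflammatory mediators, from −0.979 to −0.475 for interferon genes and from −0.403 to −0.169 for phagocytic genes. The lists that changed side were those for clock factors, dendritic markers, lysosome, glycolysis, NF-κB feedback, macrophage identity, pattern recognition and liver X receptor targets, at adjusted p from 0.0358 to 0.216.

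With the replicate number as a block (replicate block), 5297 genes were called, 5194 of them in common with the fit without it, and 253 changed at least 2-fold. Libraries with the same number had deviations from their group means correlated at −0.013, −0.058 and 0.003, and not every library correlated best with its own number, so the numbers gave no sign of pairing. The count models, their scalings and filters, a count of every row as its own feature, and the D-box search were not run. Depth limits genes listed near 0: Fkbp11 and Pianp rest on about 1.33 and 3.67 recovered reads per library labelled knockout.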

Other observations

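The genes in this part were chosen after their values were seen, and no test of enrichment was run on them.

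Genes outside the fixed lists changed as well. In the libraries labelled knockout, Slc1a4, a neutral amino acid transporter gene, rose 4.63-fold to 19.7 ± 0.653 TPM, Cth, cystathionine gamma-lyase, rose 2.38-fold to 135.8 ± 6.17 TPM, and Gpt2, mitochondrial alanine transaminase, rose 2.53-fold (SD, n = 3 each). Gdf15, a stress-induced secreted factor, rose from 2.87 ± 0.157 to 10.9 ± 0.434 TPM, and Eif4ebp1, an inhibitor of cap-dependent translation, rose 2.27-fold to 225.9 ± 10.2 TPM. Among genes known to be induced by interferon, Ly6e fell 3.70-fold, from 290.1 ± 8.57 to 78.4 ± 4.21 TPM, Samd9l fell 4.72-fold and Epsti1 fell 2.63-fold. All of these passed in limma at adjusted p from 7.19e-09 for Ly6e to 5.62e-06 for Epsti1.

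Alox5, arachidonate 5-lipoxygenase, rose 3.33-fold to 16.5 ± 0.588 TPM, and Ptafr, the receptor for platelet-activating factor, rose 2.18-fold to 28.5 ± 0.920 TPM, beside Pla2g7, which degrades that factor, and Ptgs2. Transcription factor genes that fell included Runx3, 4.04-fold lower at 2.55 ± 0.0911 TPM, and Mef2c, 2.16-fold lower than 30.2 ± 1.10 TPM in the controls. Clu, which encodes the secreted chaperone clusterin, rose 4.50-fold to 32.0 ± 1.56 TPM, and Hcar2, a receptor for nicotinic acid, rose 3.71-fold to 41.6 ± 0.641 TPM. On chromosome 6, the bin from 10 to 20 Mb held 14 tested genes with a median that differed from that of all genes by −0.501, and the bin from 20 to 30 Mb held 21 with a difference of −0.317, a pair too short to count as a run. Ndufa4, named above with a log2 fold change of −0.55, lies in the bin from 10 to 20 Mb.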
